A study of Cyprinus carpio with 6 samples.

How the data were processed

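Brain RNA of common carp was sequenced in 6 libraries, 3 labelled with no agent (control) and 3 with lead. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected on poly-T beads, and paired-end reads were sequenced; the same wording speaks of an adipose type, while the tissue label says brain. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 without their roles, and the genome build mm8, which is a mouse build. The deposited table places genes on carp RefSeq sequences, whose assembly is not given in the sources used here, and positions are printed as the table gives them. Per the file headers, the count values are the authors' reads or fragments per gene; they are whole numbers, deposited without scaling. Per the file headers, the FPKM values were made by the authors as fragments per kilobase of transcript, scaled to library size. How reads on strands, on several copies of a gene or on overlapping genes were assigned is not given, so values of duplicated and overlapping genes carry that uncertainty.

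The table held 53152 genes, 94.0% with only a locus number as symbol, and genes were named from its symbol and description columns. Gene copies were kept separate. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the robust quasi-likelihood test of lead against control, on the 32149 genes with an FPKM of at least 1 in at least 3 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The plan made before the data were examined was limma on log2(FPKM + 1), to be replaced by edgeR if counts were found, as they were. Values in the text are TMM-scaled CPM, with the SD over 3 libraries. Genes with 20 or more counts in each library of 1 group and 0 in the other group are given with a lower bound on their fold, against a floor of 3 counts over the silent group. The biological coefficient of variation was 36.6%. The labels do not say whether libraries came from separate fish, and the replicate numbers are not stated to pair them.

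Before the data were examined, 36 gene lists were fixed, 22 of processes and 14 of cell type markers, of which 35 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists. The table's GO and KEGG terms with 10 to 500 tested genes were tested for excess with Fisher's exact test, adjusted over terms and both directions. Fewer than 50 genes were called in each direction, so the 500 of smallest p in each were used, as planned. The genes to name were also fixed before the data were examined: called genes with groups that do not overlap, a mean FPKM of at least 1 and an informative description, filled by p up to 10 where fewer than 5 passed; the 2 members of smallest p of each list described; and all copies of a few genes fixed by name, among them metallothionein, alad, hmox1, gfap, ache and mbp. Genes named outside this rule were chosen after their values were seen.

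Alternatives fixed before the data were examined were limma on log2(FPKM) with 3 pseudocounts, other filters, quantile and median-of-ratios scaling, voom sample weights, no trend or robust step, DESeq2 1.42.0, the replicate number as a block, and leaving out each library. Chosen after the data were seen were library totals as the only scaling, removal of a trend on transcript length, and leaving out the genes at 0 in a group or the clock list. All 10 splits of the 6 libraries into 3 and 3 were refitted. On simulated data with the same libraries, edgeR recovered 2%, 16%, 74% and 92% of genes with true fold changes of 1.5, 2, 4 and 8, with 3 unchanged genes called. Camera called the raised list and 0 of 30 null lists. Genes were simulated independently, so this does not test the preset correlation where list members are correlated. The ribosomal list, for example, had an estimated correlation of 0.357. A gene table for another carp assembly was not used.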

Results

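Brains of common carp (Cyprinus carpio) were profiled by messenger RNA sequencing in 6 libraries, 3 from fish given no agent (control) and 3 from fish exposed to lead. The title and design text name lead-induced brain injury as the question. The labels give no dose, duration or time of sampling, and do not say whether each library came from a separate fish. The p-values therefore measure only the spread between these samples, which may be technical. Total counts over genes were 34848243, 32289182 and 31159339 in control replicates 1, 2 and 3, and 31314144, 27841520 and 32826120 in lead replicates 1, 2 and 3. Ependymin (LOC109085354), a secreted brain glycoprotein of fish named here after its values were seen, took the most counts in each of the 6 libraries, with 18730 TMM-scaled CPM (counts scaled to library size) in control replicate 1 against 5197 to 7563 in the other 5 libraries.

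The clearest difference between lead and control brains was in genes of the circadian clock, of which 8 copies rose between 3.47-fold and 9.87-fold with lead. Copies of nr1d1, a repressor at the core of the clock, of hlf, a transcription factor driven by the clock, and of cryptochrome-2 and ciart, which are clock repressors, made up these 8. Beyond them, 7 genes rose and 4 fell, among them genes with reads in every library of one group and none in the other. Genes for ribosomal proteins were slightly higher as a group. Genes for calcium signalling, for glutamatergic and for GABAergic and glycinergic synapses, for astroglia and for glycolysis were lower as groups. Markers of oligodendrocytes and microglia were also called lower, but had medians of -0.02 and 0.12 without control replicate 1. All these group calls were lost when the correlation between genes was estimated from the data. As many lists were called in 5 of the 10 splits of the libraries, the real one among them.

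Of 32149 genes tested with edgeR's quasi-likelihood test, 19 passed a Benjamini-Hochberg adjusted p of 0.05, 15 higher and 4 lower with lead. At an unadjusted p under 0.05 there were 5241 genes, 2421 higher and 2820 lower, where 1607 would arise by chance. This balance rests on the scaling: 1470 were higher and 3831 lower with library totals only, a setting chosen after the data were seen. With limma on log2(FPKM + 1), which also changes the test and the measure, 1631 were higher and 4016 lower. Without control replicate 3, 2988 genes had an unadjusted p under 0.05. The libraries of both groups did not overlap for 7869 genes, or 24.5%, against 10% by chance for 3 libraries against 3. Leaving out lead replicate 1 left 2 genes called (1 higher, 1 lower), leaving out lead replicate 2 left 3 (2 higher, 1 lower). Leaving out control replicate 3 left 10, with 0 lower by edgeR against 1588 genes lower at an unadjusted p under 0.05. Without control replicate 1, 16 genes were higher and 1 lower, and without lead replicate 3, 8 were higher and 10 lower. Each of these fits kept the filter of an FPKM of at least 1 in at least 3 libraries. Genes at 0 in lead thus went untested where a control library was left out. The same held for genes at 0 in control where a lead library was left out. The counts higher and lower therefore reflect the filter as well as the test. DESeq2 on all 6 libraries called 1324 genes (607 higher, 717 lower).

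Among clock genes, the hlf copy LOC109105462 rose from 17.5 ± 1.45 TMM-scaled CPM (SD, n = 3) in control to 108.5 ± 7.07 (SD, n = 3) in lead brains, a log2 fold change of 2.63 (SE 0.14, edgeR adjusted p = 0.00151). This copy lies on sequence NC_031727.1 from 20204945 to 20210329 on the plus strand, as the table gives it. The second hlf copy, LOC109073116, went from 36.7 ± 8.33 to 180.4 ± 5.37 CPM (SD, n = 3 each), a log2 fold change of 2.30 (SE 0.18, edgeR adjusted p = 0.0132). Of 4 nr1d1 copies tested, 3 rose, with log2 fold changes of 3.30 (LOC109098115), 2.48 (LOC109046528) and 1.79 (LOC109051193). In LOC109098115 the mean was 7.92 ± 3.49 CPM in control and 78.2 ± 15.9 in lead brains (SD, n = 3 each; edgeR adjusted p = 0.0448). Both cryptochrome-2 copies rose, LOC109066089 from 24.3 ± 5.09 to 93.1 ± 13.7 CPM and LOC109050575 from 27.6 ± 5.72 to 98.6 ± 11.4 (SD, n = 3 each; edgeR adjusted p = 0.0246 for either copy). The ciart copy LOC109111947 rose by 2.46 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0351). All 3 lead libraries lay above all 3 control libraries for each of these 8 copies. Their log2 fold changes stayed between 1.46 and 3.64 over 20 alternative settings. Their calls were less stable: 4 of the 8 were called without control replicate 1, 4 without control replicate 3, 1 without lead replicate 1, 1 without lead replicate 2 and 4 without lead replicate 3. LOC109105462 was called in each of these and lost its call in 1 of 20 alternatives (edgeR adjusted p = 0.0551). With all 6 libraries, edgeR called 0 of the 8 with no trend and not robust, 1 with the replicate block and 5 with library totals only. Limma called 4 of them on log2(FPKM + 0.01) and 8 on log2(FPKM + 1), and DESeq2 called 8.

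**Figure D1:**
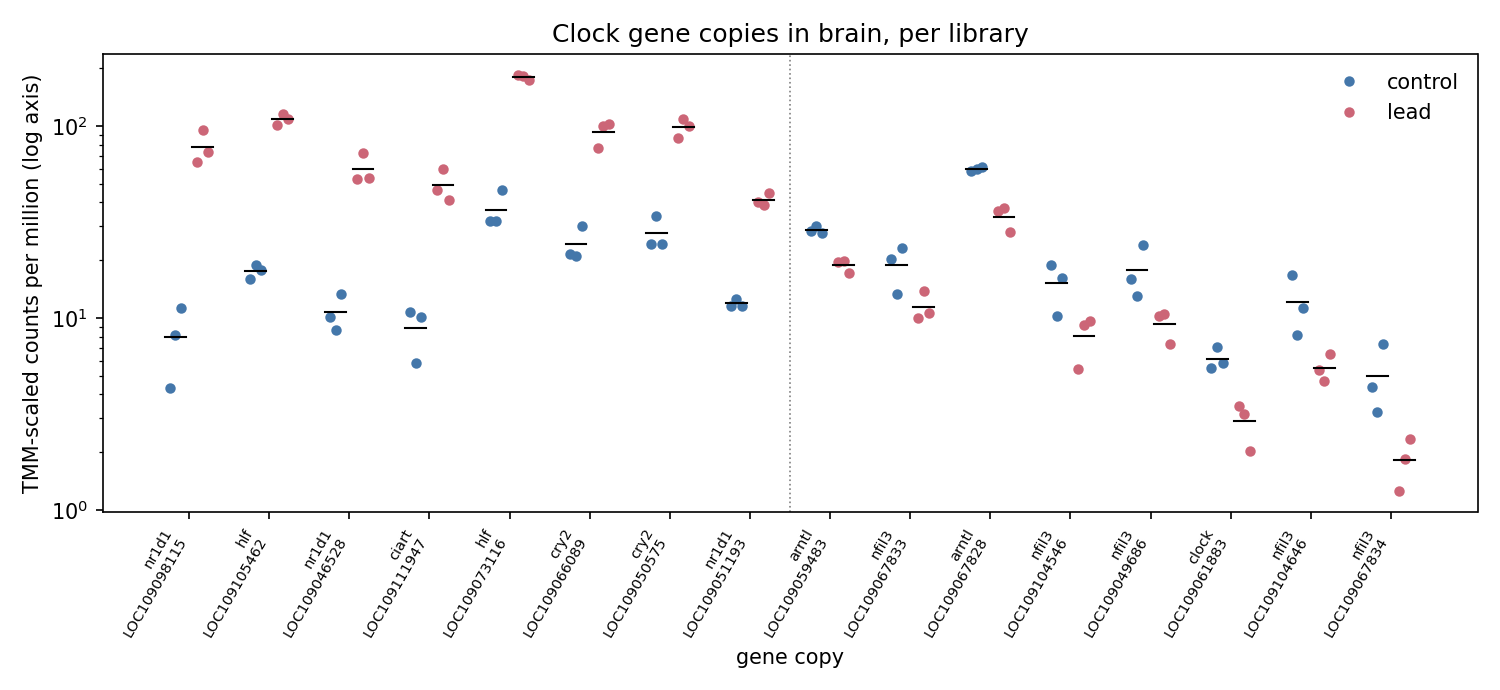
Points are TMM-scaled CPM on a log axis for each control (blue) and lead (red) library, and black bars are group means, n = 3. The 8 gene copies left of the dotted line rose with lead at an adjusted p under 0.05 over all genes, by log2 fold changes of 1.79 to 3.30. The 8 right of it are the arntl, clock and nfil3 copies that fell when adjusted over the clock list alone. They did not pass over all genes. Of the 13 members that fell by that adjustment, those of other families are not shown, such as the hlf copy LOC109100011 (-2.13). Copies that rose only by that adjustment are not shown either, such as the arntl copy LOC109090352 (0.72).

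The clock list fixed before the data were examined held 58 tested members, of which 8 rose and none fell at an adjusted p of 0.05 over all genes, while DESeq2 called 23 of them and 14 were lower at an unadjusted p under 0.05. Adjusted over the list alone, 20 members rose and 13 fell. List members named beyond the 2 of smallest p in each list, in any list, were chosen after their values were seen. Those that fell included copies of the clock activator arntl (LOC109067828, log2 fold change -0.83, SE 0.15), from 59.98 ± 1.55 to 33.8 ± 4.98 CPM (SD, n = 3 each). Of the 4 arntl copies, LOC109059483 also fell (-0.62, SE 0.15), LOC109090352 rose by the same adjustment (0.72, SE 0.25) and LOC109071277 had 0.43 (SE 0.28). A copy of nfil3, a repressor that opposes hlf at shared sites, also fell by that adjustment (LOC109104646, log2 fold change -1.13, SE 0.31). Copies within a family did not all move alike: the hlf copy LOC109100011 had a log2 fold change of -2.13 (SE 0.33), against 2.63 in LOC109105462. For cryptochrome-1, 2 of 6 copies were lower and none higher at an unadjusted p under 0.05. As a set the clock list was higher than other genes, with a median log2 fold change of 0.25 (camera adjusted p = 7.51e-11 at a preset correlation of 0.01). The adjusted p was 0.498 with an estimated correlation, the highest over 21 alternatives, the lowest being 6.28e-19. The median ranged from 0.12 with quantile normalization (adjusted p = 0.0248) to 0.44 with an FPKM of at least 5. Members lay on both sides, 33 above 0 and 25 below. The direction of the set test thus depends on how many copies of each family the list holds. Fry's test for changes in either direction gave an unadjusted p of 3.36e-05.

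Other genes that rose included LOC109106025, described as a copy of sec24a, a coat protein of vesicles leaving the endoplasmic reticulum, and LOC109079485, described as a copy of the lysine methyltransferase mettl21a. Both had a count of 0 in all 3 control libraries. LOC109106025 had 292 to 423 counts in each lead library, which makes it at least 400-fold higher with lead against a floor of 3 counts over the control group (edgeR adjusted p = 0.0132). LOC109079485 had 164 to 270 counts in each lead library and was at least 236-fold higher (edgeR adjusted p = 0.0132). LOC109086930, annotated only as an unnamed protein product and named here after its values were seen, was at least 1970-fold higher, with 1460 to 2017 counts in each lead library. LOC109106025 lost its call in 5 of 15 alternatives (adjusted p from 9.21e-16 to 0.198) and LOC109079485 in 4 of 15 (4.2e-13 to 0.179), and with a lead library left out both no longer met the filter. The splicing factor gene for LSm7 (LOC109046511), also singled out after its values were seen, rose from 23.8 ± 1.95 to 72.0 ± 5.39 CPM (SD, n = 3 each; edgeR adjusted p = 0.0132). The 3 other genes that rose (LOC109064947, LOC109066737 and LOC109107092) carry no informative description in the table.

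Of the 4 genes that fell, LOC109078941, a copy of attractin, had 143 to 170 counts in each control library and 0 in each lead library, at least 136-fold lower over the floor of 3 counts (edgeR adjusted p = 0.0246). LOC109087232, a hypothetical protein named here after its values were seen, was at least 256-fold lower. LOC109067327, described as the alpha' subunit of the cone phosphodiesterase that serves phototransduction, fell from 13.4 ± 1.85 to 0.487 ± 0.231 CPM (SD, n = 3 each), a log2 fold change of -4.76 (SE 0.41, edgeR adjusted p = 0.0132). It was the only member of the list of retina, pineal and lens markers that passed over all genes. The list as a set had a camera adjusted p of 0.954. LOC109094639, a probable glutamate receptor, fell from 9.78 ± 1.81 to 1.31 ± 0.231 CPM (SD, n = 3 each; edgeR adjusted p = 0.0246). These calls were not stable. LOC109067327 lost its call in 8 of 16 alternatives, among them without lead replicate 1 (adjusted p = 0.0537), with adjusted p from 1.54e-27 to 0.172 and log2 fold changes from -5.05 to -1.44. LOC109094639 lost it in 8 of 20, with adjusted p from 1.15e-13 to 0.133: without control replicate 1 (0.0833), control replicate 3 (0.121), lead replicate 1 (0.11), lead replicate 2 (0.106) or lead replicate 3 (0.0776), and in 3 settings with all libraries. LOC109078941 lost it in 7 of 15, among them without lead replicate 1 (0.0537) or lead replicate 2 (0.0601), with adjusted p from 1e-10 to 0.248. With a control library left out, LOC109067327 and LOC109078941 no longer met the filter. The next genes in order of p did not pass. They were olfactomedin-like 3A (LOC109100479, 0 counts in all lead libraries, at least 226-fold lower, edgeR adjusted p = 0.0546), the CaMKII delta copies LOC109100703 (log2 fold change -2.52) and LOC109065492 (-3.42), the nuclear receptor ror-beta (LOC109053270, -1.47), cullin-5 (LOC109087074, -1.85), a copy of the muscle calcium pump SERCA1 (LOC109092857, -2.33) and secretogranin-2 (LOC109045019, -1.45), with edgeR adjusted p of 0.0627, 0.0823, 0.067, 0.0688, 0.0745 and 0.0891.

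Genes of calcium signalling were lower as a set in lead brains, with a median log2 fold change of -0.35 over 141 members (camera adjusted p = 2.67e-06). The adjusted p was 0.596 with an estimated correlation, the highest over 21 alternatives from 8.22e-08. The median was -0.18 without control replicate 3. None rose or fell over all genes with edgeR, while 9 were higher and 43 lower at an unadjusted p under 0.05. Adjusted over the list alone, 22 fell and 2 rose. CaMKII genes, which encode the kinase that decodes calcium at synapses, stood at the top of the falls. LOC109100703 went from 9.94 ± 0.571 to 1.72 ± 0.58 CPM and LOC109064328, a beta subunit copy, from 16.8 ± 3.46 to 7.36 ± 1.37 (SD, n = 3 each). The sodium/calcium exchanger copy LOC109106914 (log2 fold change -1.30, SE 0.22) and the calcium pump SERCA2 copy LOC109090494 (-1.55, SE 0.27) also fell by that adjustment. The ryanodine receptor 2 copy LOC109068332 rose (0.80, SE 0.17).

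The glutamatergic list and that of GABAergic and glycinergic synapses showed the same direction. The list of monoamine and cholinergic transmission (52 members) was not called (median log2 fold change -0.06, camera adjusted p = 0.59). The glutamatergic list (134 members) had a median log2 fold change of -0.26 (camera adjusted p = 0.000306), with an adjusted p = 0.624 with an estimated correlation, the highest over 21 alternatives from 3.42e-05. The median was -0.13 without control replicate 3. Adjusted over the list alone, 12 of its members fell and 2 rose. The metabotropic glutamate receptors 5 (LOC109097667) and 3 (LOC109108952) went from 20.4 ± 2.78 to 8 ± 1.08 and from 18.0 ± 2.45 to 7.88 ± 0.587 CPM (SD, n = 3 each). The AMPA receptor subunit gene LOC109046307, for glutamate receptor 2, went from 52.0 ± 16.8 to 19.3 ± 2.53. The list of GABAergic and glycinergic synapses (90 members) had a median of -0.41 (camera adjusted p = 0.000348; adjusted p = 0.596 with an estimated correlation, the highest over 21 alternatives from 1.19e-05). No member of that list passed over all genes or adjusted over the list alone with edgeR, while 25 were lower and 1 higher at an unadjusted p under 0.05. The GABA-A receptor beta-2 copy LOC109101426 had 14.2 ± 1.88 CPM in control and 7.96 ± 0.44 in lead brains. The 1 member in the other direction was the glycine receptor alpha-4 copy LOC109069693, with 7.94 ± 2.33 and 46.9 ± 32.1 (SD, n = 3 each). Neuron markers (65 members) had a median of -0.16 (camera adjusted p = 0.0372; 0.632 as an adjusted p with an estimated correlation, from 0.000837 over 21 alternatives). The call was lost in 10 of 21 alternatives, among them limma on log2(FPKM + 1) (adjusted p = 0.0928). It was also lost without control replicate 2 (adjusted p = 0.0506), control replicate 3 (0.0683) or lead replicate 1 (0.0585). The median was -0.25 without control replicate 1 and -0.10 without control replicate 3.

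With all 6 libraries, markers of glia moved with the synaptic lists. Markers of astroglia and radial glia (30 members) had a median log2 fold change of -0.26 (camera adjusted p = 8.53e-05; adjusted p = 0.596 with an estimated correlation, the highest over 21 alternatives from 2.12e-07). The median was -0.41 without lead replicate 3. Adjusted over the list alone, 9 fell and 1 rose. The astroglial glutamate transporter genes LOC109090559 (eaat2) and LOC109085655 (eaat1) went from 37.7 ± 10.4 to 9.40 ± 3.37 and from 52.1 ± 16.3 to 12.04 ± 5.05 CPM. The gfap copy LOC109111834 went from 348.7 ± 44.0 to 188.7 ± 18.2 (SD, n = 3 each). The gap junction alpha-1 copies split, LOC109113609 with a log2 fold change of 0.60 (SE 0.12) and LOC109113611 with -0.71 (SE 0.18). Oligodendrocyte and myelin markers (38 members) had a median of -0.27 (camera adjusted p = 0.0262; adjusted p = 0.784 with an estimated correlation, from 0.000681 over 21 alternatives). The median was -0.02 without control replicate 1 (adjusted p = 0.599). The call was lost in 10 of 21 alternatives, among them without lead replicate 2 (0.0644) and with limma on log2(FPKM + 1) (0.141). Microglia and macrophage markers (36 members) had a median of -0.22 (camera adjusted p = 0.0456; adjusted p = 0.908 with an estimated correlation, from 0.0053 over 21 alternatives). The median turned to 0.12 without control replicate 1 (adjusted p = 0.641). In 12 others of the 21 alternatives the call was lost, among them without lead replicate 2 (0.543) or lead replicate 3 (0.0515). Limma on log2(FPKM + 1) was another (0.141). The median was -0.07 without lead replicate 2, -0.34 without control replicate 2, -0.36 without control replicate 3 and -0.33 without lead replicate 1. Genes for complement and acute phase proteins (31 members) had a median of -0.55 (camera adjusted p = 0.00882; adjusted p = 0.632 with an estimated correlation, from 0.000282 over 21 alternatives). The call was lost in 5 of 21 alternatives. The adjusted p was 0.0969 without control replicate 1, and the median was -0.31 without lead replicate 1. With quantile normalization the median was -0.25 (adjusted p = 0.019), and with no low-value filter it was -0.35 and not called (0.273). The C1q subunit A copy LOC109069311, a microglial complement gene in both of these lists, had 15.6 ± 8.18 CPM in control and 4.51 ± 0.798 in lead brains. It was the 1 complement member that fell adjusted over the list alone. Several members of the complement list encode C1q tumour necrosis factor-related proteins such as c1qtnf5 (log2 fold change -1.03, SE 0.33), which are secreted signalling proteins and not complement components.

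Glycolytic genes were lower as a set (53 members, median log2 fold change -0.15, camera adjusted p = 0.0204; adjusted p = 0.498 with an estimated correlation, the highest over 21 alternatives from 0.00148). The call was lost in 8 of 21 alternatives, among them without lead replicate 2 (0.0621) and with limma on log2(FPKM + 1) (0.135). Adjusted over the list alone, 8 fell and none rose with edgeR, where 4 were higher at an unadjusted p under 0.05. The 8 were alpha-enolase (LOC109047590), which went from 321.6 ± 35.9 to 140.4 ± 25.9 CPM, aldolase C (LOC109103749), from 325.6 ± 54.3 to 98.7 ± 39.5 (SD, n = 3 each), and copies of triosephosphate isomerase, glyceraldehyde-3-phosphate dehydrogenase, glucose-6-phosphate isomerase and phosphoglycerate kinase. Cytosolic ribosomal protein genes were higher as a set, with a median log2 fold change of 0.31 over 155 members, 142 of them above 0 (camera adjusted p = 9.14e-14; adjusted p = 0.649 with an estimated correlation, the highest over 21 alternatives from 1.78e-21). None passed over all genes with edgeR, 48 were higher and 0 lower at an unadjusted p under 0.05, and 3 rose adjusted over the list alone. These were the genes for L36 (LOC109060532, from 39.6 ± 3.61 to 73.3 ± 11.7 CPM), L38 (LOC109086069, from 63.3 ± 7.39 to 111.9 ± 13.4) and L30 (LOC109049042, from 31.0 ± 8.36 to 72.0 ± 11.6; SD, n = 3 each). The median of the list was 0.13 to 0.41 over the alternatives, and 0.21 without control replicate 2. Over the same alternatives, medians ran from -0.45 to -0.18 for calcium signalling, -0.38 to -0.12 for glutamatergic and -0.54 to -0.25 for GABAergic and glycinergic synapses, and -0.26 to -0.10 for glycolysis. They ran from -0.26 to -0.10 for markers of neurons, -0.41 to -0.22 for astroglia, -0.45 to -0.02 for oligodendrocytes and -0.38 to 0.12 for microglia.

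**Figure D2:**
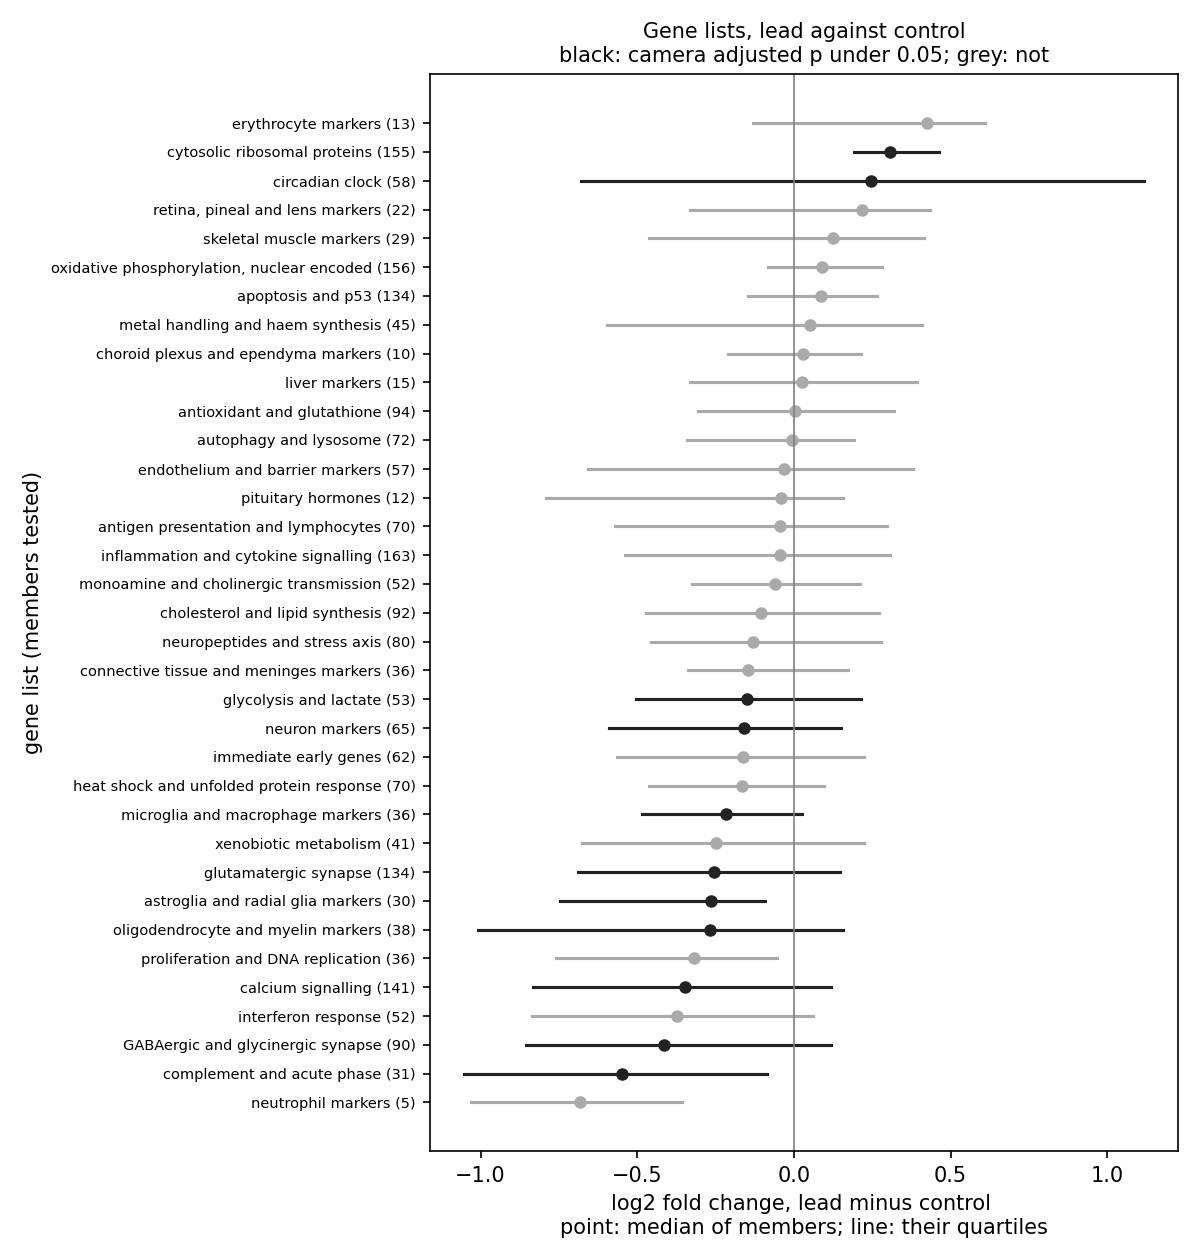
Points are the median log2 fold change, lead minus control, of the tested members of each gene list, lines run between their quartiles, and black marks a camera adjusted p under 0.05 at a preset correlation. Ribosomal proteins (0.31) and the clock list (0.25, with quartiles of -0.68 and 1.12) are the 2 black lists above 0, and 9 are below it, from -0.15 for glycolysis to -0.55 for complement.

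Lists tied to metal exposure, oxidative stress and cell death were not called by edgeR and camera with the filter and TMM scaling used throughout. The list of metal handling and haem synthesis (45 members, camera adjusted p = 0.991), that of antioxidant and glutathione genes (94 members, 0.693), that of apoptosis and p53 (134 members, 0.203), that of inflammation and cytokine signalling (163 members, 0.954), that of heat shock and the unfolded protein response (70 members, 0.0692) and that of interferon response (52 members, 0.0692) had medians of 0.05, 0.00, 0.09, -0.05, -0.17 and -0.37. The heat shock list was called lower in 7 of 19 other settings, such as quantile normalization (adjusted p = 0.0026), edgeR with an FPKM of at least 5 (0.00525) or with library totals only (0.0383), and without control replicate 3 (0.0287), over a range of 0.0026 to 0.653 in adjusted p. The interferon list was called lower in 5 of 19, which were edgeR with no low-value filter (0.0165) or with the replicate block (0.0443), and without control replicate 3 (0.000382), lead replicate 1 (0.0442) or lead replicate 3 (0.00639), with adjusted p from 0.000382 to 0.908 and medians from -0.61 to -0.14. Inflammation was called higher without control replicate 1 (adjusted p = 0.0338, up to 0.993 over the alternatives). Camera tests for a shift in 1 direction. Fry's test for changes in either direction gave an unadjusted p of 0.00315 for metal handling, 0.0188 for antioxidant and 0.00128 for apoptosis genes. It gave 0.00131 for heat shock, 0.241 for inflammation and 0.398 for interferon genes. That p was under 0.05 in 24 of the 35 lists. The metal list had a mean of -0.05 and the antioxidant list one of -0.07, opposite in sign to their medians. In the apoptosis list, the member of smallest p (LOC109049772, log2 fold change -1.23) encodes cytochrome c oxidase subunit 4. That gene also stood in the list of oxidative phosphorylation. The next was cyclin-dependent kinase inhibitor 1 (LOC109080009, 1.06). The result of the apoptosis list thus does not rest on apoptosis genes alone. The 2 members of smallest p in each list did not pass over all genes. For metal handling they were urod (log2 fold change 0.59) and ceruloplasmin (LOC109053366, -1.605). Antioxidant ones were peroxiredoxin-1 (LOC109060249, 1.42) and glutathione peroxidase 1 (LOC109078333, 0.51). Heat shock ones were hspb1 (-1.70) and heat shock 70 kDa protein 4L (-0.98). Inflammation had TNF receptor members 10B (LOC109053926, -1.07) and 6 (LOC109108031, -1.685), and interferon 2 ifih1 copies (-0.98 and -0.94). No metallothionein gene was found by name in the table. Of the genes fixed in advance, alad, the haem enzyme that lead inhibits, had 8.43 ± 1.56 CPM in control and 7.78 ± 1.07 in lead brains (SD, n = 3 each; edgeR adjusted p = 0.84). Its second copy LOC109088460 had 0.565 ± 0.584 and 0.776 ± 0.122 (adjusted p = 0.868). The haem oxygenase copy LOC109057953 had a log2 fold change of -0.92 (SE 0.43, edgeR adjusted p = 0.338). Of 5 acetylcholinesterase copies, 4 were tested. Among these, LOC109049471 had the smallest adjusted p (0.157), with 23.1 ± 2.001 CPM in control and 13.6 ± 0.30 in lead brains. The most abundant, LOC109050360, had 50.1 ± 1.70 and 46.4 ± 2.42 (adjusted p = 0.692). The 5 copies of myelin basic protein had log2 fold changes from -0.41 (LOC109066305) to 0.34 (LOC109095958). The gfap copies LOC109111834 and LOC109063688 had -0.89 (SE 0.15) and -0.49 (SE 0.14), none of them past the threshold over all genes.

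In the GO and KEGG terms carried by the table, 35 were enriched at an adjusted p under 0.05 among the 500 genes of smallest p in each direction, 11 among higher and 24 among lower genes. Among higher genes these were led by thyroid hormone receptor activity (7 of 13 genes, 0.18 by chance, adjusted p = 6.09e-07), a term that nr1d1 and nr1d2 copies carry. They included circadian regulation of gene expression (6 of 26, adjusted p = 0.000771), spliceosome (19 of 370, adjusted p = 0.000796) and ribosome (14 of 239, adjusted p = 0.00339). Among lower genes they were led by the calcium signaling pathway (28 of 393 genes, 6.69 by chance, adjusted p = 6.09e-07), calmodulin-dependent protein kinase activity (9 of 43, adjusted p = 4.67e-05) and glycolytic process (9 of 46, adjusted p = 6.56e-05). Symporter activity (10 of 66), circadian rhythm (5 of 19) and the AMPA glutamate receptor complex (6 of 52) were also among them. Without lead replicate 1, 23 terms were enriched.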

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

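The settings with library totals only, the length trend removed, genes at 0 in a group left out and the clock list left out were chosen after the data were seen. Library totals only moved the median log2 fold change of all genes from -0.01 to -0.11.

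The 19 genes called by edgeR (15 higher, 4 lower) became 1324 with DESeq2 (607 higher, 717 lower), 9 with limma on log2(FPKM + 0.01) (7 higher, 2 lower) and 30 with no low-value filter (23 higher, 7 lower). With no trend and not robust, edgeR called 0 (0 higher, 0 lower), where 4938 genes had an unadjusted p under 0.05. The genes lower were 7 with limma on log2(FPKM + 1), 7 with quantile normalization, 2 with genes at 0 in one group left out, which removes called genes by construction, and 0 with voom sample weights, where 3171 had an unadjusted p under 0.05. With the replicate number as a block (replicate block), 1 gene was called (1 higher, 0 lower) by edgeR and 6078 had an unadjusted p under 0.05, 3221 of them lower. Deviations of libraries with the same number correlated at 0.129, 0.032 and 0.08, and those of libraries with different numbers at -0.123 to 0.045. These few values do not settle whether the numbers pair samples, and the main test did not use the numbers. Leaving out 1 library gave 2 genes (without lead replicate 1) to 25 (without control replicate 2), 1 to 20 higher for the same libraries, and 0 (without control replicate 3) to 10 (without lead replicate 3) lower. These fits kept the filter of at least 3 libraries, so genes at 0 in 1 group dropped out where a library of the other group was left out. Apart from the libraries left out and the genes removed, the cause was not tested.

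The 11 lists called became 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 with fry (10 at an unadjusted p under 0.05). They were 7 with limma on log2(FPKM + 0.01), 7 with no trend and not robust, 7 with voom sample weights, and 1 of 8 testable lists with members matched by symbol only, since most symbols are locus numbers. Of 231 values of called lists under alternatives, 173 kept direction and call, 57 lost the call and 1 reversed: microglia and macrophage markers, with a median of 0.12 without control replicate 1. With each library left out in turn its lowest median was -0.36 (without control replicate 3), and over all alternatives the lowest was -0.38. Inflammation and cytokine signalling, not called, ranged from -0.19 (without control replicate 2) to 0.19 without control replicate 1, where it was called in the other direction. The cause was not tested.

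The 35 terms became 21 with limma on log2(FPKM + 0.01), 21 on log2(FPKM + 0.1), 19 on log2(FPKM + 1), 18 with no trend and not robust and 16 with quantile normalization, and 23 (without lead replicate 1) to 32 (without control replicate 1) with a library left out. The cause was not tested. Of 241 values of called named genes, 156 kept direction and call and 85 lost the call. The authors' own p-values were not run as an alternative, since the table used here has none.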

Other observations

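Tests chosen only after the result was seen are those of clock phase, of scaling on the clock genes, and of the share of neurons, and the genes of the next paragraph were chosen after their values were seen.

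Other genes stood apart between the groups without passing edgeR's threshold over all genes. The cytochrome P450 1A1 copy LOC109046471, which metabolises foreign compounds, had 0.642 ± 0.207 CPM in control and 23.8 ± 18.9 in lead brains (SD, n = 3 each; edgeR adjusted p = 0.137), and the P450 1B1 copies split, LOC109100558 with a log2 fold change of 1.93 and LOC109100547 with -0.99. An MHC class I gene, LOC109062092, had 88.55 to 478.3 CPM in lead libraries and 0.675 to 9.74 in control libraries. The small heat shock protein gene LOC109075469 (hspb1) had 52.95 ± 18.9 and 16.3 ± 1.89 CPM (SD, n = 3 each), and the heat shock factor copies LOC109088181 and LOC109052618 had log2 fold changes of 1.48 and 0.73. The gonadotropin beta-1 gene LOC109094212 had one of 1.56 and cga, the shared alpha subunit by its symbol, one of 2.13. The calmodulin copy LOC109100202 (0.71) and the NMDA receptor copy LOC109061150 (0.90) were higher at an unadjusted p under 0.05, against the direction of their lists.

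The limbs of the clock had medians of opposite sign, with exceptions in both. The 39 copies grouped with nr1d1 (nr1d, hlf, tef, ciart, period and cryptochrome families) had a median log2 fold change of 0.53 (18 higher and 5 lower at an unadjusted p under 0.05). In that group cryptochrome-1 (-0.566) and period 1 (-0.237) had medians below 0, and the other families had medians from 0.184 (period 2) to 2.507 (nr1d1). The 14 copies of the opposite limb (arntl, clock and nfil3) had a median of -0.67 (1 higher, 8 lower). The limbs thus had a difference of 1.202, where the highest of the other 9 splits gave 0.606. A factor per library cancels in this difference and cannot give it, and with quantile normalization, which is no such factor, it was 0.93, so scaling is argued against. An earlier form of this check, on the median of the whole clock list, could not decide because the limbs go both ways. These values are consistent with groups sampled at different phases of the daily clock, which lead may have shifted or which a different hour of collection may have set. The labels give no hour, so these values do not separate an effect of lead from the hour.

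Genes with 20 or more counts in each library of 1 group and 0 in the other numbered 30, 10 in lead and 20 in control, among them a CaMKII alpha copy (LOC109093811, 46 to 52 counts in control libraries), and 5 of the 30 were called. Inherited presence or absence of genes cannot be told apart from an effect of lead: the other splits gave 9 to 20 such genes, and the bound of 28.9 set beforehand was wrong by design, because the labels do not say whether each group came from 1 family, and neighbouring genes such as LOC109079485 and LOC109079482, 8.7 kb apart and both in lead only, are not independent. Reads given to another copy or an overlapping gene cannot be told apart either, since 23.3% of the 30 genes had such a gene that gained at least 0.5 of the loss, against a median of 36.7% in random sets, and how reads on copies were assigned is not given. The number of such genes was 83 with a minimum of 10 counts and 10 with a minimum of 50, both chosen after the data were seen.

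Ribosomal protein genes were higher, while the calcium list and the glutamatergic and the GABAergic and glycinergic synapse lists were lower. Transcript length is argued against as the whole cause: with a length trend removed, the median of the ribosomal list was 0.361 (0.308 before), and that of the pooled synapse and calcium lists was -0.313 (-0.331 before), with each list still called. A lower share of neurons, which would raise markers of other cell types, cannot be told apart. The 161 markers of astroglia, oligodendrocytes, microglia and endothelium had a median of -0.206 (95% interval -0.303 to -0.101, all genes -0.009). But without control replicate 1 it was -0.021 (-0.101 to 0.1, all genes 0.009), where astroglia had -0.225 and microglia 0.124. Both intervals come from resampling the markers, so they do not measure the spread between libraries. Without lead replicate 2 the pooled median was -0.147. An effect of lead stays open, as do a different hour of collection and a different part of the brain taken, neither of which the labels allow to be tested.

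The 6 libraries make 10 splits into 3 and 3, so that no share under 0.05 can be had. The real split gave 19 genes, 11 lists and 35 terms, and the highest of the other splits 7, 12 and 33. As many genes came from 1 of the 10 splits, the real one, as many lists from 5, and as many terms from 1.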
